A study of Solenopsis invicta with 64 samples.

How the data were processed

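Gene expression was measured by RNA sequencing in the brain and the ovary of 32 winged, unmated queens (gynes) of the red imported fire ant, Solenopsis invicta. Per the labels' protocols, the animals were collected in the field as they left their mounds to mate and were frozen there. Per the labels, each library came from the RNA of a single brain or a single ovary, extracted with DNase treatment and turned into sequencing libraries by the Smart-seq2 method, which amplifies cDNA by PCR and uses no molecular identifiers. Brains and ovaries were extracted with different column kits, so the kit and the tissue cannot be separated. The 64 libraries fall into 8 groups of 8: in each tissue, monogyne SB/SB, polygyne SB/SB, polygyne SB/Sb and polygyne Sb/Sb. Monogyne colonies have a single egg-laying queen and polygyne colonies have several. SB and Sb are the variants of a supergene, a block of linked genes inherited as a unit, which lies on chromosome 16.

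Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with STAR 2.5.3a and assigned to genes with featureCounts, whose version is not given in the sources used here. The genome build and annotation behind the alignment are also not given in the sources used here. The 64 deposited files, 1 per library, hold raw counts per gene: whole numbers with a different total in each library and no normalization by the authors. Each file lists 15710 genes, of which 15512 carry LOC symbols and 198 are transfer RNAs with 0.00018% of the counts. Gene symbols were matched to a gene table of the assembly UNIL_Sinv_3.0, which has 16 chromosomes. Of the LOC symbols, 11895 were in that table and held 94.8% of the counts, 11799 had a chromosome, and 970 were on chromosome 16. The other 3617 symbols could not be placed. The gene table gave chromosome membership but no product names. Gene order was the rank of the table's start values within each chromosome. The 25 gene lists fixed beforehand (pathways, cell types, mobile elements and others) were defined by symbols and product names, matched 0 genes, and were therefore not tested. Synonyms identified 9 genes of the files, among them the vitellogenin receptor and genes for odorant-binding proteins, insulin receptors and detoxification enzymes. The supergene marker Gp-9 and the vitellogenins could not be identified.

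Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Normalization was by TMM, low-count genes were removed with filterByExpr by group at a minimum count of 10, and quasi-likelihood F-tests were adjusted by Benjamini-Hochberg, with a call at an adjusted p under 0.05. All 32 libraries of a tissue were fitted together, with 1 coefficient per group. The filter kept 10704 genes in the brain and 10691 in the ovary. In each tissue 5 comparisons were made: polygyne SB/SB against monogyne SB/SB, SB/Sb against SB/SB within polygyne animals, Sb/Sb against SB/Sb, Sb/Sb against SB/SB, and polygyne SB/Sb against monogyne SB/SB. A further contrast asked whether SB/Sb lies off the mean of the polygyne homozygotes on the log2 scale. Brain and ovary were compared in 1 fit of all 64 libraries with the animal as a block, since the title codes link the brain and the ovary of an animal; 11708 genes were tested there. In the same fit, the difference between an effect in the brain and in the ovary was tested for each comparison. Every p-value treats the animals as separate from each other. Title numbers recur among the 24 polygyne animals (9 numbers, 7 with all 3 genotypes) but none is shared with the monogyne animals, so social form and any property that goes with the number cannot be told apart.

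Enrichment of chromosome 16 among changed genes was tested by two-sided Fisher's exact tests against the other chromosomes. The odds ratio is given with its 95% interval, and p-values were adjusted over the 10 comparisons. Genes without a chromosome were left out. All Fisher's tests here count genes as independent, although they are measured in the same animals and those of the supergene are inherited together. Their p-values are therefore not strict. Measures of libraries were compared by two-sided exact permutation tests of the difference in means, adjusted over the family stated beside them. Values per gene are counts per M (CPM) scaled with the TMM factors, given as the mean and standard deviation (SD) over the libraries of a group; n = 8 unless stated. Log2 fold changes come from the edgeR fits with their standard error (SE). For a group with no counts, fold changes are lower bounds against 3 counts over the whole group; these bounds and the other intervals cover counting error only.

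Total counts ranged from 9.46 to 26.9 M in the brain (median 19.6 M). In the ovary they ranged from 10.1 to 22.6 M (median 17.4 M), except for the polygyne SB/SB ovary of animal 104D, which had 0.0736 M. That library met a depth limit fixed beforehand, under the tissue's median total divided by 3, for an alternative fit without it. CPM means and SD of the polygyne SB/SB ovary leave it out (n = 7). Pairs of libraries within a group (224 pairs) were checked for duplicated counts; the lowest chi-square per degree of freedom was 18.3, so no pair was a copy.

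Before the data were examined, the groups, comparisons, tests, most alternatives and the rule for named genes were fixed. The rule took from each comparison the 12 called genes of each direction with the smallest p whose sign also held in a fit of only the groups compared. It took 8 per direction for brain against ovary, 6 for each tissue difference and 6 for the genes off the log2 mean, and it added the genes known by a synonym. Its part on product names could not be applied. Alternatives were the size factors of DESeq2 (RLE), no low-count filter, a mean count of at least 50, the Wald test of DESeq2 1.42.0, only the groups compared, limma 3.58.1 voom with sample quality weights, the log2 library total as a covariate, a block by title number, and the fit without 104D. Fits without the brain libraries 1E, 16C, 16D and 30A, which lie far from the other brains in the principal components or in the share of their top genes, were added after the data were seen. So were the fits of both tissues without the 104D ovary or without the animal block, and the title block without 104D. Principal components used the 1000 most variable genes on log2 CPM with a prior count of 2. Plots were drawn with matplotlib 3.10.9.

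The method was tested on simulated counts before the real comparisons. With 100 genes changed by a log2 fold of 1 and 100 by 2, the brain design recovered 25% and 66%, with 5 false calls among 96. The ovary design recovered 60% and 87%, with 4 false calls among 151. With nothing changed, the brain design made 1 call and the ovary design none, by edgeR, the only tool run on simulated counts. Of 200 genes with a planted tissue difference of log2 2, 58% were recovered.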

Results

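Brain and ovary RNA was sequenced from 32 fire ant gynes, 8 in each of 4 groups: monogyne SB/SB, polygyne SB/SB, polygyne SB/Sb and polygyne Sb/Sb. The design asks how social form and supergene genotype go with gene expression in each tissue. Brain libraries held 15.5 to 26.9 M counts in monogyne SB/SB, 9.46 to 23.5 M in polygyne SB/SB, 10.9 to 23.8 M in SB/Sb and 14.3 to 25.2 M in Sb/Sb. Ovary libraries held 13.2 to 22.6 M in monogyne SB/SB, 11.8 to 21 M in SB/Sb and 10.1 to 20.5 M in Sb/Sb. Polygyne SB/SB ovaries reached 20.3 M, with 12.3 M in the lowest but 1. The lowest was the ovary of animal 104D, with 73573 counts and 1457 genes detected; its top 10 genes held 52.8% of its counts. The leading principal component took 14.2% of the variance in the brain and the next took 10.1%. In the ovary the leading component took 67.2% and separated 104D from the rest; without 104D it took 31.5%.

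Brain and ovary differed at most genes, and the genes known by a synonym showed how sharply. LOC105203994, an odorant-binding protein gene on chromosome 6, stood at 1140 ± 239 CPM in the monogyne brain and 0.945 ± 0.338 in the monogyne ovary (log2 difference 9.58 ± 0.16 SE over all groups, adjusted p = 3.35e-31). The vitellogenin receptor gene LOC105200757, whose product takes yolk protein into the oocyte, was higher in the ovary, by a log2 difference of -3.94 ± 0.44 for brain minus ovary (adjusted p = 6.44e-10). The glutathione S-transferase gene LOC105197561 was 2.84-fold higher in the brain (adjusted p = 5.64e-11) and the cytochrome P450 gene LOC105195645 (CYP6A14) was 21.3-fold higher in the ovary (adjusted p = 3.3e-07). The insulin receptor gene LOC105195102 (InR-2) was 2.98-fold higher in the ovary (adjusted p = 1.11e-05), and InR-1, LOC105207962, did not differ (log2 0.18 ± 0.53, adjusted p = 0.766). Among the genes with the smallest p, LOC105204669 on chromosome 3 averaged 1070 ± 285 CPM in the monogyne brain and 0.00707 ± 0.02 in the monogyne ovary, where only 232A had any counts. LOC105194572 on chromosome 2 and LOC105193824 on chromosome 16 were the reverse, at 9.35 ± 7.64 and 6.03 ± 2.14 CPM in the monogyne brain against 1930 ± 106 and 1440 ± 121 in the ovary. Of 11708 genes tested, 4309 were higher in the brain and 5279 in the ovary. The median log2 difference over all genes was -0.18 with TMM and 0.05 with RLE, so the balance of the directions depends on the scaling.

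How many genes differed with social form in the brain depended on the tool. Polygyne SB/SB and monogyne SB/SB brains, which share the genotype, differed at 1 gene of 10704 by edgeR. LOC105196801 on chromosome 2 rose from 43.9 ± 9.44 CPM in monogyne to 93.7 ± 26.9 in polygyne SB/SB brains, a log2 change of 1.09 ± 0.18 (adjusted p = 0.00768). Its level in polygyne SB/Sb (73.7 ± 14.6) and Sb/Sb brains (75.2 ± 15.1) was also above the monogyne mean. No gene was called lower by edgeR, while 1974 genes of either direction had an unadjusted p under 0.05. DESeq2 called 358 genes (316 higher, 42 lower), voom with quality weights 3, and edgeR on only these 16 libraries 0 (1738 at an unadjusted p under 0.05). At least 1 gene was called in 7 of 100 regroupings of the same libraries, so the single call is not set apart from chance.

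A single copy of Sb went with the appearance of transcripts in the brain. All 27 genes that differed between SB/Sb and SB/SB polygyne brains were higher in SB/Sb, and several were close to 0 without Sb. LOC105205139 on chromosome 2 rose from 0.579 ± 1.42 to 37.7 ± 16.8 CPM (log2 6.0 ± 0.82, adjusted p = 4.47e-05), and LOC105194018 on chromosome 3 from 0.0482 ± 0.0812 to 7.22 ± 2.92 (log2 6.94 ± 0.72, adjusted p = 5.6e-07). Library 16D raised both SB/SB means, which were 0.0783 ± 0.0977 and 0.0235 ± 0.0448 CPM without it; a fit without the brains 1E, 16C, 16D and 30A gave LOC105205139 a log2 change of 9.42 (adjusted p = 5.42e-11). The unplaced LOC105203531 had no counts in the polygyne SB/SB brains and 1.88 ± 0.894 CPM in SB/Sb, at least 91.1-fold higher. LOC105206713 on chromosome 2 and LOC105204491 on chromosome 4 had the same form (log2 7.26 and 6.97), with SB/SB means that rested on 1 library each, 30E (0.046 CPM, 0 without it) and 20D (0.0453, 0.00665 without it). On chromosome 16, LOC105193135 rose from 13.9 ± 3.19 to 38.5 ± 9.33 CPM (log2 1.47 ± 0.20, adjusted p = 3.34e-05), LOC105194434 from 0.324 ± 0.269 to 7.29 ± 2.13 (log2 4.49 ± 0.62, adjusted p = 5.71e-05) and LOC105194501 from 4.71 ± 5.03 (3.12 without 107E) to 70.8 ± 33.3 (log2 3.91, adjusted p = 0.00524). LOC105194441 and LOC105199315, also on chromosome 16, rose by log2 2.85 and 4.4, the second from 0.345 CPM, or 0.21 without 19D. No gene was called lower by edgeR, with 422 of either direction at an unadjusted p under 0.05; DESeq2 called 36 higher and 1 lower, and voom 39 and 2. The count was 14 among genes with a mean count of at least 50 and 12 with only these groups.

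Most genes that edgeR called for the second copy of Sb in the brain were lower. Of 17 genes that differed between Sb/Sb and SB/Sb brains, 16 were lower in Sb/Sb. LOC105202812 on chromosome 16 fell from 15.7 ± 16.6 CPM in SB/Sb to 0.255 ± 0.163 in Sb/Sb, a log2 change of -5.94 ± 0.66 (adjusted p = 2.61e-06). LOC105206526 fell from 115 ± 47.3 to 25.1 ± 8.9 CPM, LOC105199343 from 54.4 ± 12.5 to 18.8 ± 3.14, LOC105196490 from 285 ± 176 to 44.1 ± 13.9 and LOC105199321 from 5.13 ± 2.17 to 0.279 ± 0.474 (0.133 without 104G), all on chromosome 16. The unplaced LOC105201495, LOC105207492 and LOC105207481 fell by 1.51, 4.05 and 2.18 on the log2 scale. LOC105193135 was the gene that rose, from 38.5 ± 9.33 to 74.6 ± 11.2 CPM (log2 0.95 ± 0.19, adjusted p = 0.0178). LOC105202823, called lower by log2 -5.08, averaged 81.1 ± 186 CPM in SB/Sb, an SD above its mean, and 15.5 ± 9.56 without 107A. DESeq2 called 27 genes, 5 higher and 22 lower, and voom called 20 with a more even balance, 9 higher and 11 lower.

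Across both steps, 103 genes differed between Sb/Sb and SB/SB polygyne brains, 65 higher and 38 lower in Sb/Sb. LOC105193135 rose 5.37-fold (log2 2.42 ± 0.20, adjusted p = 1.58e-09). LOC105206832 on chromosome 1 rose 2.35-fold, from 151 ± 28 to 355 ± 68 CPM, LOC105206510 on chromosome 16 rose 4.65-fold, from 5.23 ± 3.34 to 24.3 ± 4.24, and LOC105199588 on chromosome 8 rose 5.81-fold, from 6.42 ± 3.96 to 37.3 ± 11.3. LOC105205139 reached 66.1 ± 15.6 CPM (log2 6.81 ± 0.85, adjusted p = 2.56e-06; SB/SB mean 0.579, or 0.0783 without 16D), LOC105194018 reached 13.5 ± 2.96 and LOC105206713 reached 16.3 ± 2.18; LOC105203531 was at least 138-fold higher and LOC105207189 at least 87.7-fold. Among the lower genes, LOC105202812 fell 134-fold from 34.3 ± 18.2 CPM (log2 -7.06 ± 0.69, adjusted p = 2.66e-08), LOC105199321 fell 37.0-fold (to 0.279 CPM, or 0.133 without 104G), LOC105196490 fell 10.1-fold and LOC105199343 fell 4.42-fold. LOC105203076, at 101 ± 22.5 and 52.7 ± 4.81 CPM, changed less (log2 -0.94 ± 0.15). None of the genes known by a synonym was called; the vitellogenin receptor gene LOC105200757 changed by log2 1.04 ± 0.83 (adjusted p = 0.547). DESeq2 called 572 genes, with the balance turned to 122 higher and 450 lower. Voom called 100 higher and 38 lower.

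Polygyne SB/Sb brains differed from monogyne SB/SB brains, a contrast of both social form and genotype, at 23 genes, 21 of them higher. LOC105205139 rose by log2 6.76 ± 0.85 (adjusted p = 1.36e-05), LOC105194018 by 6.08 and LOC105196479 on chromosome 2 by 7.96, from 0.0892 (0.0057 without 232A) to 21 ± 7.34 CPM. LOC105199339 on chromosome 16 rose 29.9-fold, from 0.27 ± 0.249 to 8.20 ± 1.98 CPM. LOC105203531 and LOC105194902 were at least 106-fold and 130-fold higher. The lower genes, LOC105203076 (118 ± 26 to 70.6 ± 11.4 CPM, adjusted p = 0.012) and LOC105206540 (209 ± 31.2 to 114 ± 25.1, adjusted p = 0.0137), both lay on chromosome 16. Of the higher genes, 19 were also higher in Sb/Sb against SB/SB polygyne brains, a comparison that shares no library with this one. For independent calls 0.128 were expected (Fisher's exact p = 8.71e-42). Both comparisons came from the same fit, and polygyne animals of different genotypes share title numbers. Their calls are therefore not independent, and this p-value is not a strict test. Higher genes were the majority with each tool, by a margin that varied: DESeq2 called 55 higher and 7 lower, and voom 52 and 24, with 8 of its lower genes on chromosome 16 and 10 on other chromosomes. It was 12 and 2 at a mean count of at least 50, and 12 and 1 with only these groups.

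**Figure D1:**
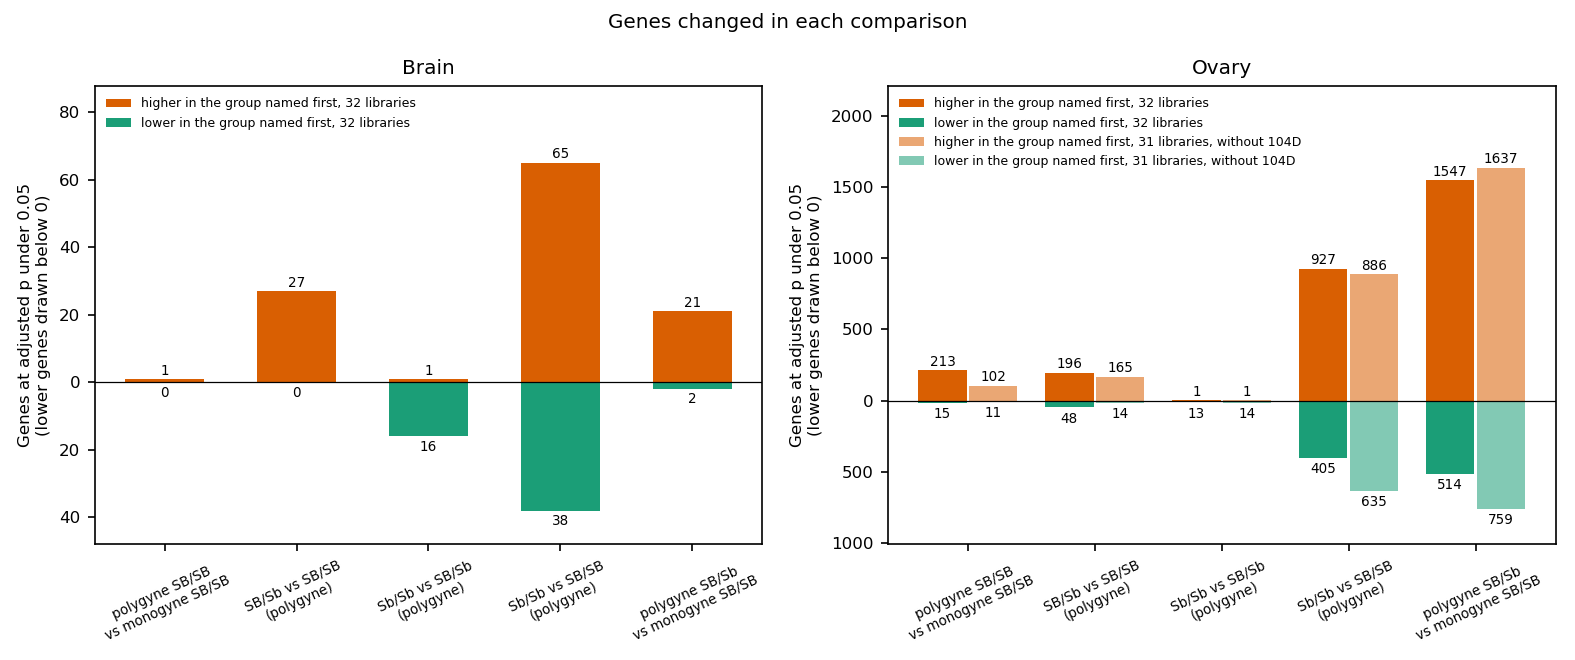
Bars give the number of genes called at an adjusted p under 0.05 in each comparison, higher genes above 0 and lower genes below it, in the brain (left) and the ovary (right). Paler ovary bars leave out library 104D, without which the ovary calls fell from 228 to 113 between polygyne and monogyne SB/SB and rose from 1332 to 1521 between Sb/Sb and SB/SB.

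The changed genes of the brain gathered on chromosome 16, which carries the supergene. In Sb/Sb against SB/SB brains, 44 of 786 tested genes of chromosome 16 (5.6%) differed and 32 of 8456 on the other chromosomes (0.378%), an odds ratio of 15.6 (95% interval 9.61 to 25.6, Fisher's exact adjusted p = 5.06e-27). Of the 44, 28 were higher and 16 lower. Genes of the same animals are not independent replicates, so the p-values for chromosome 16 are not strict. No regrouping of the animals tested this excess. The size of the excess depended on how genes were called: with DESeq2 the odds ratio was 3.18 (2.49 to 4.03), with 42 higher and 59 lower, and at an unadjusted p under 0.01 it was 2.72 (2.17 to 3.41), with 46 higher and 66 lower. The other settings gave 13.3 to 20.3. The odds ratio was 13.1 (5.16 to 33.9, adjusted p = 7.67e-08) for SB/Sb against SB/SB and 7.59 (2.44 to 22.1, adjusted p = 0.000407) for SB/Sb against monogyne. Between Sb/Sb and SB/Sb, 10 changed genes were on chromosome 16 and 0 of 17 on another chromosome, with 7 unplaced; the odds ratio had a lower bound of 24.3 (adjusted p = 4.7e-11). DESeq2 called 13 genes on chromosome 16 and 5 elsewhere, and voom 7 and 3. In the gene order of chromosome 16, all 44 changed genes of Sb/Sb against SB/SB lay between places 401 and 1200, where 467 genes were tested. Among 294 tested genes at places 1 to 400 edgeR called none. These limits were chosen after the values were seen.

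In the ovary, the changed genes were also more frequent on chromosome 16. Between Sb/Sb and SB/SB, 169 of 789 tested genes of chromosome 16 (21.4%) and 958 of 8461 others (11.3%) were called, an odds ratio of 2.13 (1.77 to 2.57, adjusted p = 8.77e-14). DESeq2 gave 2.15 and an unadjusted p under 0.01 gave 1.99, against 3.18 and 2.72 in the brain; a difference between the tissues was not tested. It was 2.28 (1.51 to 3.34, adjusted p = 0.000135) for SB/Sb against SB/SB, and 5.07 (3.55 to 7.16) with voom. Between Sb/Sb and SB/Sb ovaries, 11 of the 14 changed genes lay on chromosome 16 and 1 on another, LOC105201567 on chromosome 7 (odds ratio 120, 17.3 to 4980, adjusted p = 4.7e-11). Neither comparison with monogyne animals passed the test with 32 libraries (odds ratio 1.14 and adjusted p = 0.674 for SB/SB, 1.14 and 0.21 for SB/Sb); for SB/Sb, RLE and voom gave adjusted p of 0.0294 and 1.52e-06. By place, 124 of 466 genes (26.6%) between 401 and 1200 and 43 of 299 (14.4%) between 1 and 400 were called in Sb/Sb against SB/SB.

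**Figure D2:**
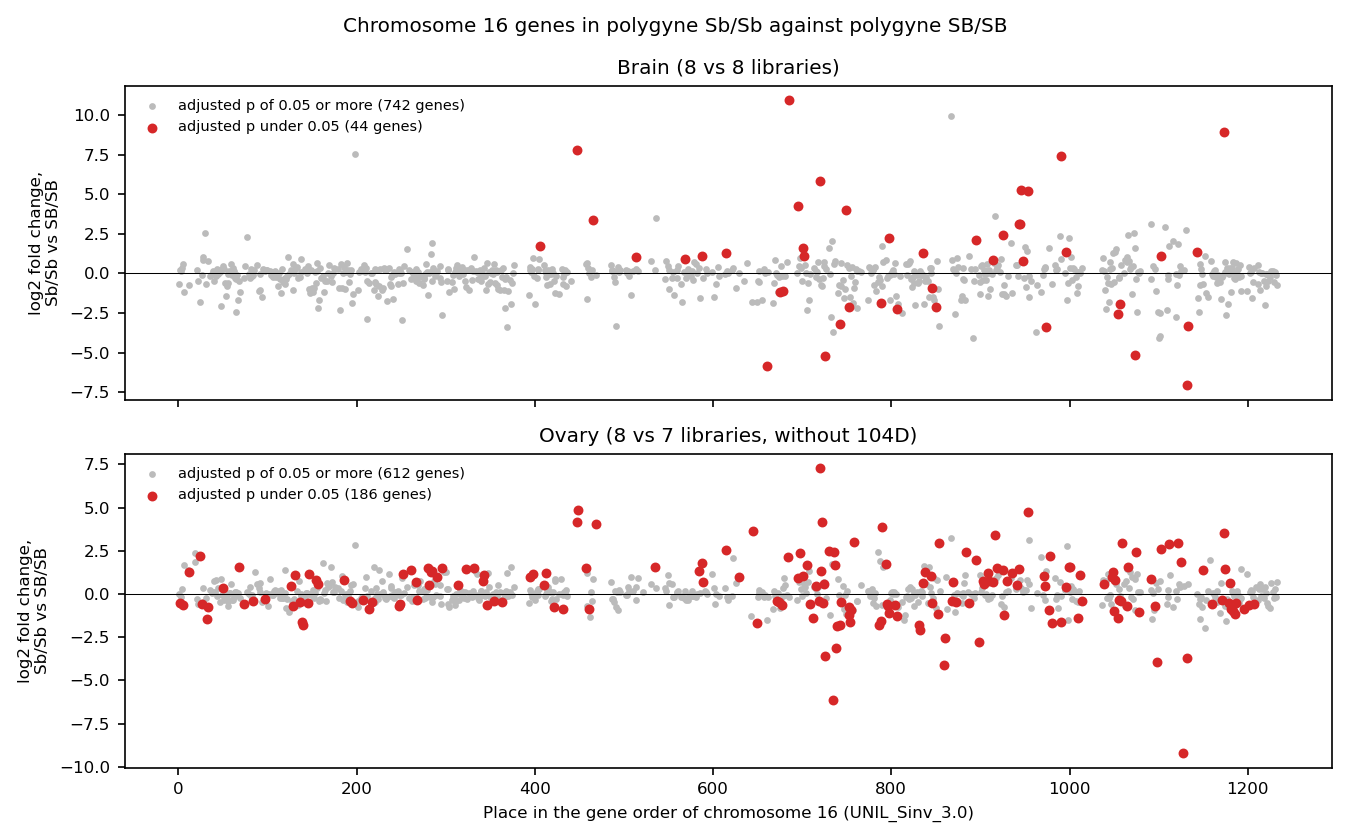
Each point is a tested gene of chromosome 16, placed by its rank in the gene order (horizontal) and its log2 fold change in Sb/Sb against SB/SB polygyne animals (vertical), with red for an adjusted p under 0.05. All 44 called genes of the brain lie between places 401 and 1200, while the 186 called genes of the ovary, fitted without 104D, spread further.

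SB/SB ovaries of the 2 social forms differed at 228 of 10691 genes, and 104D decided many of them: without it 102 genes were higher and 11 lower in polygyne SB/SB. Of the 213 genes higher with all libraries, 99 were also called without 104D. The 114 that lost their call had a median absolute log2 change of 2.43 with 104D and 1.42 without it. LOC105200507 on chromosome 6 rose from 11.6 ± 1.61 to 24.4 ± 6.34 CPM (n = 7; log2 1.08 ± 0.16 without 104D, adjusted p = 0.00284), LOC105201938 on chromosome 1 from 67.4 ± 9.13 to 133 ± 40.7, LOC105192966 from 27.7 ± 8.8 to 61.7 ± 19.3 and LOC105195789 on chromosome 16 from 71.3 ± 9.47 to 117 ± 21.4. Among the lower genes, LOC105197899 on chromosome 10 fell from 165 ± 10.3 to 114 ± 16.6 CPM (log2 -0.52 without 104D, adjusted p = 0.0231), and LOC105194853 on chromosome 1 from 21.3 ± 4.79 to 11.4 ± 3.6. The other 8 of the 12 genes named as higher lost their call without 104D: LOC105200215, for example, went from log2 10.54 to 0.44 (adjusted p = 0.247) and LOC105202145 from 9.05 to -0.18. The vitellogenin receptor gene LOC105200757 varied widely in polygyne SB/SB ovaries (226 ± 232 CPM against 58.5 ± 12.7 in monogyne) and was not called (log2 1.92 ± 0.65, adjusted p = 0.0844). RLE in place of TMM gave 490 genes, DESeq2 922, the 2 groups alone 1091 and the library total as a covariate 384. Voom called 172 (119 higher, 53 lower), and only 66 of them were among the 228.

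Several of the genes that appeared in the brain with 1 copy of Sb did so in the ovary. LOC105205139 rose from 0.0437 ± 0.045 CPM in polygyne SB/SB to 11 ± 3.57 in SB/Sb ovaries (log2 7.86 ± 0.48, adjusted p = 8.82e-11), and LOC105194018 was at least 81.1-fold higher. LOC105196479 rose 32-fold, from 1.78 ± 1.64 (1.17 without 1E) to 57.0 ± 14.9 CPM, and on chromosome 16 LOC105193825 rose 6.13-fold, from 2.98 ± 0.751 to 18.3 ± 7.14, LOC105199315 from 0.162 (0.0916 without 20D) to 12.9 ± 4.01, and LOC105194501 from 2.84 ± 1.31 to 35.8 ± 19.4. LOC105193135 rose from 40.5 ± 6.4 to 77.8 ± 6.83 CPM (log2 0.95 ± 0.13). The odorant-binding protein gene LOC105203994 rose from 1.52 ± 0.739 to 3.53 ± 1.04 CPM (log2 1.21 ± 0.28, adjusted p = 0.00981). Of the genes named as lower, LOC105203027 on chromosome 16 kept its call without 104D (194 ± 36.8 to 98.9 ± 29.1 CPM, log2 -0.99, adjusted p = 0.000774). With all libraries 196 genes were higher and 48 lower; without 104D the numbers were 165 and 14, and 10 of the 48 remained. With only these groups the count was 80, and 6 of 100 regroupings of all libraries called as many as the 244 (3 of 100 without 104D, for 179). Of 23 genes called higher in SB/Sb brains and tested in both tissues, 16 were also higher in SB/Sb ovaries. For independent calls 0.343 were expected (Fisher's exact p = 5.78e-25). The brains and ovaries came from the same animals, so their calls are not independent and this p-value is not a strict test.

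Between Sb/Sb and SB/Sb ovaries, 14 genes differed, 13 of them lower. As many were called in 5 of 100 regroupings of the same libraries (13 of 100 without 104D, for 15 genes), so the count is not set apart from chance. The regroupings compare only the number of genes, not which genes are called. Of the 14, 11 lay on chromosome 16 and 1 on another chromosome (odds ratio 120), a share that the regroupings did not test. LOC105202816 on chromosome 16 fell 170-fold, from 116 ± 71.4 to 0.665 ± 1.28 CPM (0.228 without 15G; log2 -7.41 ± 0.74, adjusted p = 1.47e-07), and LOC105202812 fell 7.29-fold, from 48.1 ± 22.9 to 6.59 ± 2.93 (log2 -2.87 ± 0.27, adjusted p = 9.36e-08). LOC105203065 fell from 261 ± 69.8 to 125 ± 25 CPM, LOC105193228 from 34.9 ± 6.67 to 18.3 ± 2.66 and LOC105199321 from 6.09 ± 2.52 to 0.947 ± 1.02, all on chromosome 16. LOC105194441 rose from 34.1 ± 7.77 to 61.6 ± 15 CPM (log2 0.85 ± 0.17, adjusted p = 0.0189). The genes LOC105202812, LOC105199321, LOC105199336 and LOC105205915 were lower in both tissues. The share of higher genes was 7.14% with TMM and 26.3% with RLE, which added higher genes. The balance depended on the tool: DESeq2 called 12 higher and 21 lower, voom 15 and 16, and the fit of these groups alone 6 genes, all lower.

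Homozygous Sb ovaries differed widely from SB/SB ovaries. LOC105205139 stood at 22 ± 7.96 CPM in Sb/Sb (log2 8.85 ± 0.49, adjusted p = 8.78e-12), LOC105193825 rose 11.8-fold to 35.1 ± 9.93, LOC105193135 rose 2.69-fold to 108 ± 22 and LOC105199315 rose 157-fold to 28.2 ± 8.79 (SB/SB mean 0.162, or 0.0916 without 20D). LOC105194018 was at least 169-fold higher and LOC105204491 at least 470-fold. On chromosome 16, LOC105202816 fell 559-fold from 396 ± 75 CPM (to 0.665, or 0.228 without 15G), LOC105202812 fell 12.6-fold from 84.8 ± 12, LOC105203065 fell 3.96-fold from 518 ± 92.9 and LOC105203027 fell 3.32-fold from 194 ± 36.8. Off chromosome 16, LOC105197697 on chromosome 10 fell 2.87-fold, from 88.2 ± 21.1 to 30.7 ± 15.2 CPM. The odorant-binding protein gene LOC105203994 rose 2.93-fold to 4.48 ± 0.933 CPM (log2 1.55 ± 0.28, adjusted p = 0.000383), and the glutathione S-transferase gene LOC105197561 stood at 929 ± 816 CPM against 431 ± 67.8 (log2 1.17 ± 0.36, adjusted p = 0.0281). The vitellogenin receptor gene LOC105200757 and InR-2, LOC105195102, were not called (log2 -0.41 and -0.30, adjusted p = 0.738 and 0.779). In all, 927 genes were higher and 405 lower with all libraries, and 886 and 635 without 104D. Long noncoding RNA genes were called at 41 of 140 tested (33 higher, 8 lower) and pseudogenes at 9 of 39, all 9 higher. Of the genes higher in the brain and tested in both tissues, 43 of 57 were also higher in the ovary (4.59 expected for independent calls, Fisher's exact p = 8.39e-36). Of 31 lower genes, 12 were lower in both (1.12 expected, Fisher's exact p = 3.09e-10). Both tissues came from the same animals, so their calls are not independent. The fit of these groups alone called 476 higher and 121 lower. Voom called 1193 higher and 1122 lower, so the excess of higher genes was not seen with it.

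Polygyne SB/Sb and monogyne SB/SB ovaries differed at 2061 genes, 1547 higher and 514 lower in SB/Sb. The balance varied with the fit: 1637 higher and 759 lower without 104D, 1960 and 459 with DESeq2, 1882 and 1178 with only these groups, and 1043 and 740 with voom. LOC105205139 was at least 535-fold higher, LOC105196479 rose 72.9-fold (0.765 ± 0.844 to 57.0 ± 14.9 CPM; 0.479 without 222A) and LOC105193825 rose 5.76-fold (3.16 ± 0.779 to 18.3 ± 7.14). LOC105194062 on chromosome 14 rose 3.18-fold, from 17.9 ± 4.13 to 56.9 ± 26.6 CPM. LOC105203994 rose 3.72-fold (log2 1.89 ± 0.27, adjusted p = 3.6e-05), and the odorant-binding protein gene LOC105195107 on chromosome 5 rose from 1.18 ± 0.755 to 5.34 ± 4.71 CPM (log2 2.18 ± 0.57, adjusted p = 0.0103). InR-2, LOC105195102, rose from 5.94 ± 1.01 to 18.6 ± 20.4 CPM, an SD above the mean and 11.9 without 16C (log2 1.65 ± 0.55, adjusted p = 0.0351). LOC105203027 fell 2.32-fold, LOC105206510 fell 2.10-fold, LOC105203065 fell 2.04-fold and LOC105197357 fell 1.58-fold, all on chromosome 16, and LOC105200010 on chromosome 5 fell 3.50-fold. Of the genes higher here, 473 were also higher in Sb/Sb against SB/SB polygyne ovaries, which share no library with this comparison (134 expected for independent calls). For lower genes the overlap was 138 against 19.5 expected, and 269 against 44.6 without 104D. The calls compared here came from the same fit, and polygyne animals share title numbers, so the calls are not independent.

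Most genes called between the polygyne homozygotes had the heterozygote in between. On chromosome 16, SB/Sb lay at a median of 44.7% of the way from SB/SB to Sb/Sb in CPM for the 28 higher genes of the brain and 48.8% for the 16 lower ones. In the ovary without 104D the medians were 54.5% for 98 higher genes and 59.9% for 88 lower genes. These genes were chosen for a difference between the homozygotes, and a false call would also tend to leave SB/Sb in between. The medians therefore describe the called genes and do not test for an effect of dose. Monogyne SB/SB ovaries lay nearer to polygyne SB/SB than to Sb/Sb at 865 of the 886 higher genes (97.6%) and 597 of the 635 lower genes (94.0%). In the brain this held for 60 of 65 higher genes and 20 of 38 lower genes. Tested on the log2 scale, SB/Sb lay above the mean of the homozygotes at 6 genes in the brain and 14 in the ovary, 20 entries in all; LOC105205139 in the ovary had the smallest p (log2 3.43 ± 0.30, adjusted p = 2.29e-07). As many genes were called in 18 of 100 regroupings of the same libraries in the brain and 41 of 100 in the ovary (9 of 100 without 104D, for 13 genes), so these counts are not set apart from chance. A gene at the midpoint in CPM lies above the log2 mean by arithmetic, most of all when 1 homozygote is near 0. LOC105205139 in the ovary, at 0.0437, 11 and 22 CPM in SB/SB, SB/Sb and Sb/Sb, was such a gene. The direction of these calls therefore does not show a departure from an additive effect in CPM. In CPM, 12 of the 20 had an SB/Sb mean within 1.5 times of the midpoint of the homozygotes, and 5 were over 2 times the midpoint. These 5 SB/Sb means exceeded both homozygotes. LOC105201567 and LOC105204265 in the ovary averaged 17.1 ± 30.1 and 25.3 ± 44.7 CPM, with an SD above the mean. Without 15A they were 6.9 and 10.2. LOC105202823 in the brain (81.1 ± 186 CPM, 15.5 without 107A) and LOC105194637 in the ovary (2.38 ± 3.21) also had an SD above the mean. LOC105200663 in the ovary averaged 0.724 ± 0.541 CPM, against 0.0078 in SB/SB and 0.647 in Sb/Sb. No gene was called below the mean of the homozygotes by edgeR in either tissue (328 genes of the brain and 353 of the ovary had an unadjusted p under 0.05 in either direction), while DESeq2 called 1 in each tissue.

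**Figure D3:**
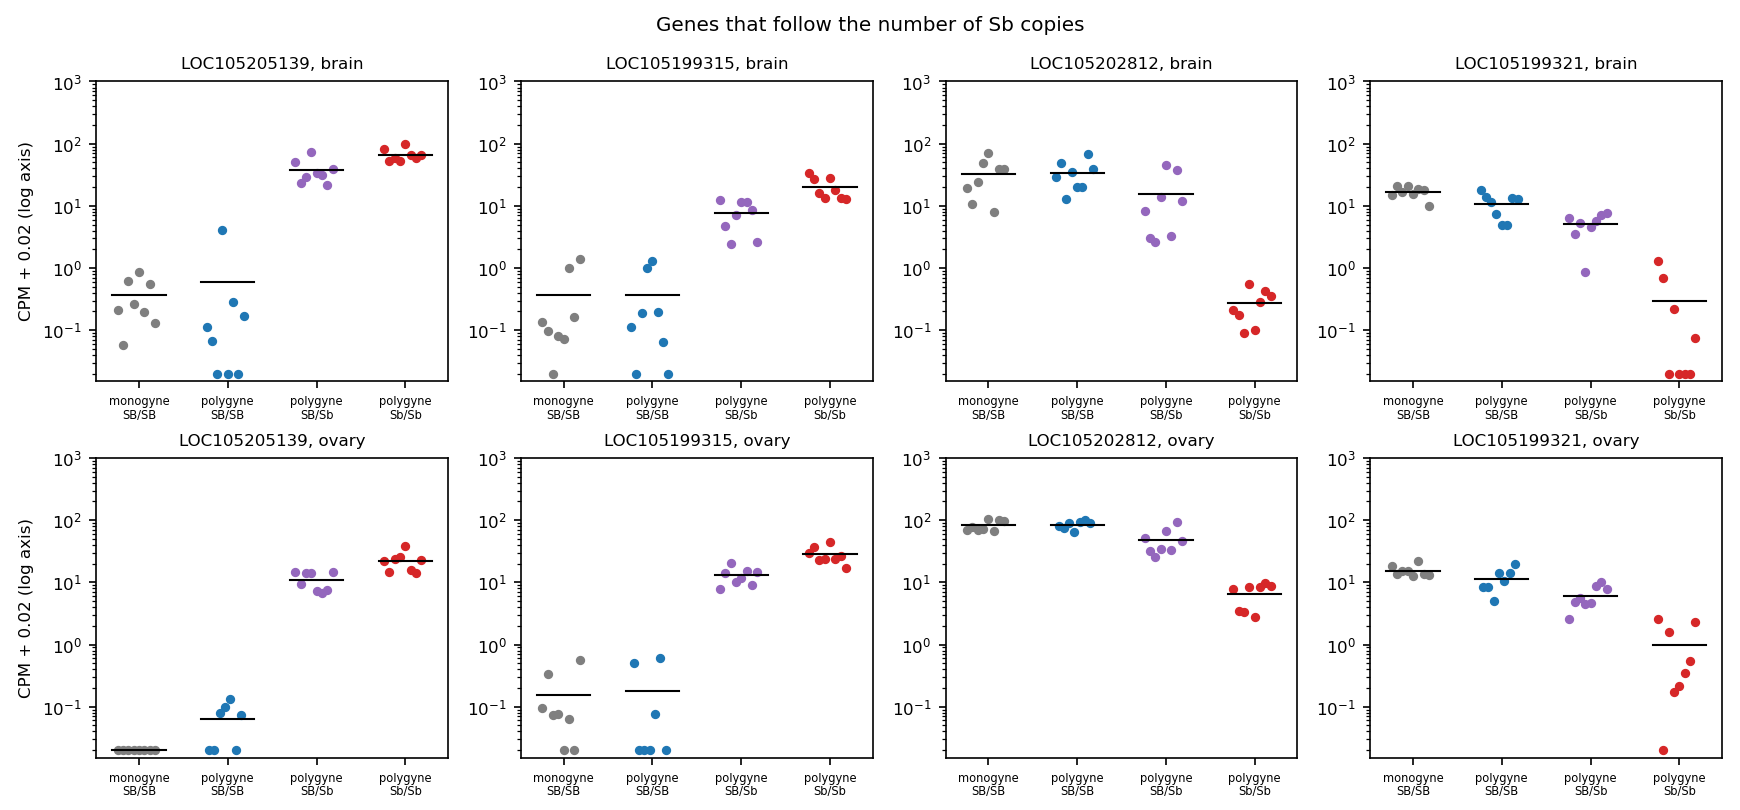
Points are libraries, with CPM plus 0.02 on a log axis, for 4 genes in the brain (top) and the ovary (bottom) by group; black lines are group means, and the ovary library of 104D is left out. LOC105205139 and LOC105199315 are near 0 in both SB/SB groups and rise with the number of Sb copies, and LOC105202812 and LOC105199321 fall with it.

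Ovaries with more copies of Sb had transcripts of more genes. After all libraries were thinned to 9 M counts, 11220 ± 109 genes were detected in monogyne SB/SB ovaries, 11347 ± 115 in polygyne SB/SB (n = 7), 11640 ± 124 in SB/Sb and 11863 ± 136 in Sb/Sb. Every Sb/Sb ovary (11671 to 12054) was above every polygyne SB/SB ovary (11198 to 11520; exact permutation test, p = 0.000155, adjusted over 10 tests p = 0.000777). SB/Sb ovaries differed from SB/SB (exact adjusted p = 0.00207) and from Sb/Sb (exact adjusted p = 0.0136). In the brain the means ran from 10638 ± 694 to 10719 ± 495, with no exact adjusted p under 0.959. At the same time genes specific to the ovary were lower. For 363 genes at least 16-fold above the brain in monogyne animals, the median log2 difference from the monogyne ovary mean was -0.12 ± 0.11 (SD over libraries, n = 7) in polygyne SB/SB, -0.45 ± 0.39 in SB/Sb and -0.73 ± 0.54 in Sb/Sb. For 3300 genes within 2-fold of the brain it was -0.05 ± 0.07, -0.03 ± 0.07 and -0.06 ± 0.04. TMM scaling holds a set of genes this broad near 0, so these values are no separate control. Of the ovary-specific genes, 97 were called lower and 21 higher in Sb/Sb against SB/SB without 104D.

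**Figure D4:**
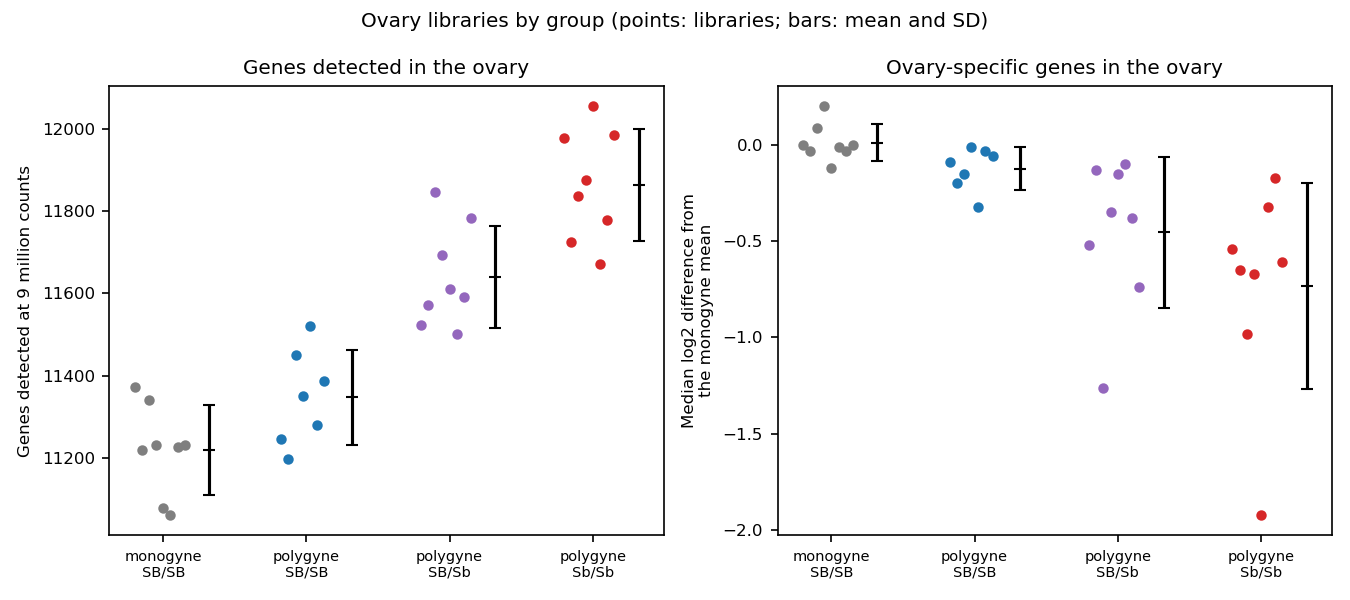
Points are ovary libraries by group, with the mean and SD beside them: on the left the number of genes detected at 9 M counts, on the right the median log2 difference of 363 ovary-specific genes from the monogyne mean. Genes detected run from 11220 on average in monogyne SB/SB to 11863 in Sb/Sb, and the ovary-specific median from 0.01 to -0.73; 104D is left out.

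The effect of Sb differed between the tissues at a set of genes that includes opposite changes. LOC105194811 on chromosome 16 rose in the brain from 0.0291 ± 0.0823 CPM in SB/SB, where only the brain of 104D had any counts, to 6.59 ± 2.04 in Sb/Sb and fell in the ovary from 157 ± 23.3 (n = 7) to 51.2 ± 20 (log2 of the brain effect minus the ovary effect 9.34 ± 1.00, adjusted p = 9.7e-07). LOC105206510 rose in the brain from 5.23 ± 3.34 to 24.3 ± 4.24 CPM and fell in the ovary from 61.6 ± 14.5 to 29.0 ± 9.7 (log2 3.48 ± 0.38, adjusted p = 9.7e-07). LOC105194434 rose in the brain from 0.324 ± 0.269 to 12.6 ± 3.05 CPM and stood at 13.2 ± 6.06 and 17.2 ± 7.25 in the ovary (log2 5.31 ± 0.64, adjusted p = 4.2e-06). LOC105202812 fell further in the brain than in the ovary (log2 -3.33 ± 0.48, adjusted p = 0.000178). Between Sb/Sb and SB/SB the effect differed at 335 genes, 100 of them (29.9%) higher in the brain than in the ovary; with RLE it was 479 genes and 19.8%. Without the 104D ovary the count was 795, with 458 in favour of the brain. Of these 795, 89 lay on chromosome 16 and 772 were tested in both tissues; LOC105194811 and LOC105206510 were called in opposite directions, 296 were called in the ovary alone and 15 in the brain alone. For SB/Sb against SB/SB, 3 genes differed, LOC105194434, LOC105194811 and LOC105206510, and for SB/Sb against monogyne 6. EdgeR called 0 genes for polygyne against monogyne SB/SB (527 at an unadjusted p under 0.05) and 0 for Sb/Sb against SB/Sb (892); no other tool was run on these fits. Without the animal block the first of these counts was 51 and the second 0 (1306 at an unadjusted p under 0.05).

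**Figure D5:**
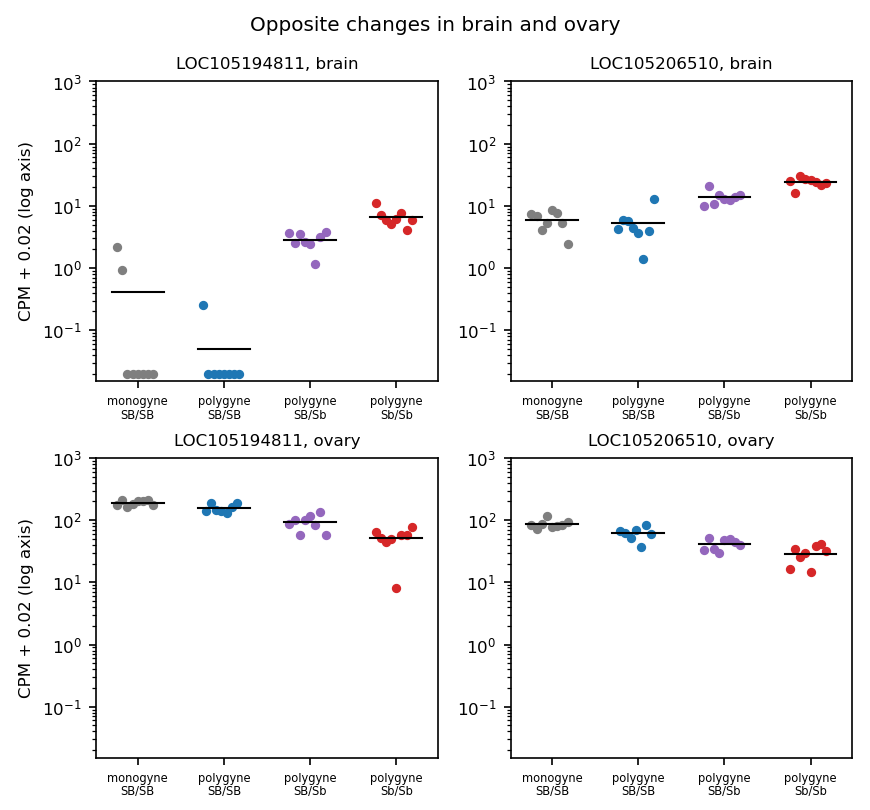
Points are libraries, with CPM plus 0.02 on a log axis, for LOC105194811 and LOC105206510 in the brain (top) and the ovary (bottom) by group; black lines are group means, and the ovary library of 104D is left out. Both genes rise with the number of Sb copies in the brain and fall in the ovary.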

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

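The tests on lost reads in this part were chosen after the results were seen; the tissue differences and the search for samples far from the others were planned.

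The effect of Sb differed between brain and ovary at genes on chromosome 16 and elsewhere. For SB/Sb against SB/SB, 3 genes differed: LOC105194434 (log2 of the brain effect minus the ovary effect 4.86 ± 0.63 SE, adjusted p = 6.99e-05), LOC105194811 (7.15 ± 1.02, 0.000285) and LOC105206510 (2.09 ± 0.38, 0.0134). Between Sb/Sb and SB/SB it was 335 genes (795 without the 104D ovary, 89 of them on chromosome 16), with LOC105194811 (9.34 ± 1.0), LOC105206510 (3.48 ± 0.38), LOC105194434 (5.31 ± 0.64), LOC105202812 (-3.33 ± 0.48), LOC105199339 (5.83 ± 0.89) and LOC105202363 on chromosome 13 (-2.72 ± 0.42) having the smallest p. For SB/Sb against monogyne SB/SB, 6 genes differed: LOC105199339 (6.22 ± 0.87), LOC105194434 (3.92 ± 0.58), LOC105206510 (2.38 ± 0.36), LOC105194811 (5.23 ± 0.85), LOC105199976 on chromosome 5 (-2.55 ± 0.49) and the odorant-binding protein gene LOC105203994 on chromosome 6 (-1.64 ± 0.34, adjusted p = 0.0473). The other genes named here lie on chromosome 16; its share among all tissue differences was not tested.

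A technical explanation for changed genes on chromosome 16 is that reads of the Sb haplotype, where its sequence differs from the reference, are lost in the alignment. If the reference carries SB, such loss only lowers counts in Sb/Sb and by its premise gives no higher genes. The build behind the alignment is not given, so this premise was not checked. Chromosome 16 had an excess of higher genes. In the brain it was 28 of 786 against 21 of 8456 elsewhere (odds ratio 14.8, Fisher's exact p = 4.72e-18). In the ovary without 104D it was 98 of 798 against 622 of 8530 (odds ratio 1.78, Fisher's exact p = 2.08e-06). Under the premise, loss is then not the whole source of the changed genes on chromosome 16. Loss is also taken to be equal in both tissues, which was not tested. At 2 of 85 chromosome 16 genes lower in Sb/Sb in the brain or the ovary and tested in both, loss can then not be the whole cause. LOC105194811 and LOC105206510 were lower in the Sb/Sb ovary without 104D (log2 -1.64 ± 0.25 and -1.11 ± 0.19) and higher in the Sb/Sb brain (7.41 ± 1.26 and 2.22 ± 0.31). Of the other 83, 28 (33.7%) had an effect that differed between the tissues. Loss alone would not give this, but the difference was about as frequent among genes of other chromosomes chosen the same way (141 of 480, 29.4%; odds ratio 1.22, 0.716 to 2.06, Fisher's exact p = 0.438), so a change across the ovary on top of loss stays open. For these 83 genes, loss of reads and lower expression of the Sb copy cannot be told apart here, since no genome sequence was used. A difference in regulation between the haplotypes stays open for all of these genes and was not tested.

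Single libraries far from the rest of their group, by the gap to the nearest library divided by the range of the group, were found in 11 of 36 tests of library measures and 35 of 428 tests of gene values; chance gives about 1 in 20. Library 104D of the polygyne SB/SB ovaries stood apart in total counts (0.604), genes detected (0.974), the share of its top 10 genes (0.914) and the leading principal component (0.966). In the share of the top 10 genes, the brains of 239A (0.531; 13%), 15D (0.83; 17.1%), 30A (0.944; 43.8%) and 104G (0.695; 13.2%) and the ovaries of 233A (0.679; 9.9%) and 19G (0.853; 18.4%) were the highest of their groups. The SB/Sb ovary of 15A had the most genes detected in its group (0.571; 12198).

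Among gene values in the brain, monogyne libraries stood apart at LOC105193825 (222A, 0.583), LOC105196479 (232A, 0.91), LOC105196490 (207A, 0.553), LOC105199321 (240A, 0.561), LOC105203504 (222A, 1) and LOC105204491 (233A, 1). Polygyne SB/SB brains did so at LOC105193825 (19D, 1), LOC105194902 (1E, 0.685), LOC105196479 (15D, 0.792; 5.05 CPM against at most 0.326), LOC105198369 (16D, 0.66), LOC105199336 (16D, 0.551), LOC105204491 (20D, 0.818), LOC105205139 (16D, 0.811; 4.09 CPM against at most 0.26) and LOC105206713 (30E, 1). A ratio of 1 marks the only library of its group with any counts of the gene. SB/Sb brains stood apart at LOC105199321 (16C, 0.605), LOC105199343 (104A, 0.547) and LOC105199589 (107A, 0.591), and the Sb/Sb brain of 104G at LOC105196479 (0.526).

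In the ovary, monogyne libraries stood apart at LOC105196588 (222A, 0.539), LOC105200010 (233A, 0.604) and LOC105206625 (207A, 1). Polygyne SB/SB ovaries did so at LOC105200010 (15D, 0.62), LOC105200215 (1E, 0.593), LOC105202816 (1E, 0.64), LOC105204917 (1E, 0.723), LOC105205051 (30E, 0.585), LOC105206713 (1E, 1) and LOC105207137 (16D, 0.579). SB/Sb ovaries did so at LOC105198369 (19A, 0.564), LOC105202816 (15A, 0.697; 3.19 CPM against at least 61.4) and LOC105205051 (5A, 0.652). Sb/Sb ovaries did so at LOC105200507 (5G, 0.637), LOC105200949 (15G, 0.671), LOC105201344 (104G, 0.683) and LOC105204265 (107G, 0.533). No explanation was tested for these single values.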

How the results depend on the processing

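The fits without the brains of 1E, 16C, 16D and 30A, without the 104D ovary in the fits of both tissues, without the animal block and with the title block but without 104D were chosen after the data were seen. For named genes, 1700 of 1882 values under an alternative kept their direction and their side of the threshold, 154 lost the call, 6 gained one and 22 changed sign; with RLE all 231 were kept. Of the gene counts, 35 of 52 in the brain, 37 of 56 in the ovary and 25 of 31 in the fits of both tissues stayed within 1.5 times. Of 79 tests of chromosome 16, 68 kept direction and side. Where no reason is given, the cause was not tested.

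DESeq2 called 358 genes between polygyne and monogyne SB/SB brains, 27 for Sb/Sb against SB/Sb, 572 for Sb/Sb against SB/SB, 62 for SB/Sb against monogyne and 11 off the log2 mean of the homozygotes. In the ovary it called 922 between the SB/SB groups and 33 for Sb/Sb against SB/Sb. Voom called 3, 41 (SB/Sb against SB/SB), 76 (SB/Sb against monogyne) and 18 (off the mean) in the brain, and 31 (Sb/Sb against SB/Sb) and 2315 (Sb/Sb against SB/SB) in the ovary.

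RLE called 490 genes between the SB/SB ovaries, and the library total as a covariate 384. A mean count of at least 50, which tests fewer genes, gave 14 for SB/Sb against SB/SB, 14 for SB/Sb against monogyne and 3 off the mean in the brain, 8 off the mean in the ovary, and 12 tissue differences for SB/Sb against monogyne.

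With only the groups compared, which uses fewer libraries, the brain gave 0 between the SB/SB groups (edgeR; 1738 at an unadjusted p under 0.05; DESeq2 and voom, run on all 32 libraries, called 358 and 3), 12 for SB/Sb against SB/SB and 13 for SB/Sb against monogyne. The ovary gave 1091, 80, 6 (Sb/Sb against SB/Sb) and 597 (Sb/Sb against SB/SB). Without the 4 brains the SB/SB groups differed at 4 genes. Without 104D the SB/SB ovaries differed at 113 genes, and the effect of Sb/Sb against SB/SB differed between tissues at 795. Without the animal block the tissue differences numbered 51 for the SB/SB groups, 76 for SB/Sb against SB/SB, 518 for Sb/Sb against SB/SB and 33 for SB/Sb against monogyne.

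The block by title number gave 10 genes for Sb/Sb against SB/Sb brains. In the ovary it gave 89 for SB/Sb against SB/SB (91 without 104D), 5 for Sb/Sb against SB/Sb (8 without), 822 for Sb/Sb against SB/SB and 8 off the mean (8 without). Libraries with the same number were alike in part, after removal of the group means. In the brain 9 of 22 such pairs had r over 0.1, with a mean r of 0.1 against -0.012 for pairs with other numbers. In the ovary it was 13 of 22, with a mean r of 0.2 against -0.017. In the brain 9 and in the ovary 6 of 23 libraries were nearest to a library with their own number. On the leading ovary component without 104D, the SB/SB, SB/Sb and Sb/Sb libraries of number 15 lay at 7.3, 25 and 59.2. Those of number 20 lay at -29.5, -15.1 and 6, and those of number 19 at -29.9, -16.9 and 24.5. For number 16, SB/Sb was the highest (14.8, 48.2 and 18.6). The likeness was partial, and the numbers were not taken as pairs. The main fits therefore leave out what libraries of the same number share, and their p-values do not allow for it.

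For polygyne against monogyne SB/SB, the odds ratio of chromosome 16 crossed 1 while no setting passed the test. In the brain the adjusted p was 0.613 with DESeq2, 0.331 without the 4 brains and 0.259 at an unadjusted p under 0.01. In the ovary it was 0.469 with RLE, 0.906 at a mean count of at least 50, 0.141 with DESeq2, 0.365 with only the groups, 1 with voom and 0.115 at an unadjusted p under 0.01. For SB/Sb against monogyne ovaries it passed with RLE (0.0294) and voom (1.52e-06), with the other settings between 0.0501 and 0.224.

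The sign changes of single genes were all in ovary comparisons that include 104D. For polygyne against monogyne SB/SB, LOC105198603 went to -0.08 with voom and -0.05 with the covariate, LOC105198576 to -0.02 with voom, and LOC105202145 to -0.15 with DESeq2, -0.07 with voom, -0.23 with the covariate and -0.18 without 104D. For SB/Sb against SB/SB, LOC105200215 went to 0.09 with DESeq2, 0.27 with voom, 0.01 with the covariate, 0.06 without 104D and 0.21 with the title block and without 104D. LOC105200949 went to 0.06 with DESeq2, 0.01 with voom, 0.02 without 104D and 0.03 with the block and without it. LOC105198576 went to 0.08 with voom. LOC105202721 went to 0.4 with DESeq2, 0.28 with voom, 0.2 with the covariate, 0.35 without 104D and 0.3 with the block and without it.

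The leading principal component took 20.8% in the brain and 71.9% in the ovary with all tested genes, and 31.5% in the ovary without 104D. The limit on low libraries left out no brain, and only the groups compared could not apply to brain against ovary, so neither was run there. In simulated counts, planted changes of log2 1 were recovered at 25% in the brain and 60% in the ovary, although the brain had the higher median total (19.6 M against 17.4 M), so depth alone does not set what can be called. How much depth limits the calls was not tested.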

Other observations

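The tests in this part were chosen after the results were seen, apart from the fits with the library total and without 104D, which were planned. A set of genes had transcripts in animals with Sb and next to none in SB/SB animals of either social form. Taking genes called higher in Sb/Sb with both SB/SB means under 5% of the Sb/Sb mean, the brain had 15 and the ovary, without 104D, 28, with 10 in both. Of the 10, 1 was on chromosome 16 (LOC105199315), 7 on other chromosomes, among them LOC105205139, LOC105194018, LOC105206713, LOC105204491 and LOC105198369, and 2 unplaced. LOC105204208 on chromosome 3 rose in the brain from 0.637 CPM in polygyne SB/SB (0.402 without 104D) to 9.38 ± 3.55 in SB/Sb and 25.3 ± 5.57 in Sb/Sb. In the ovary, the pseudogene LOC105205176 on chromosome 11 rose from 0.43 to 3.76 ± 2.12 and 10.7 ± 9.21 CPM. LOC105197535 and LOC105202373 were exceptions: they reached 14.9 ± 41.3 and 24.5 ± 66.1 CPM in Sb/Sb ovaries, with an SD above the mean, and 0.184 and 0.544 in SB/Sb. Single libraries made these means, which were 0.254 without 19G and 1.11 without 5G in Sb/Sb, and 0.0807 and 0.355 without 15A in SB/Sb.

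The genes that changed in Sb/Sb ovaries were also set apart by tissue. Genes higher in Sb/Sb than in SB/SB ovaries without 104D had a median brain-minus-ovary log2 difference of 0.71 in monogyne animals (886 genes), and the lower genes had -1.74 (635 genes), against -0.35 for all 10797 tested. The Sb/Sb ovary of 19G had the lowest median of ovary-specific genes, -1.92.

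For the genes near 0 in SB/SB animals, reads from another organism or tissue could be present in some animals whatever their genotype. The SB/Sb libraries, which are outside the contrast that chose the genes, argue only against such sporadic reads for the set: for the median gene, 100% of the 8 lay above every SB/SB library, in the brain and in the ovary, and all 8 did so at 12 of 15 and 20 of 28 genes. Sporadic reads stay open for the genes at which at most 4 of the 8 did so, LOC105204349 in the brain and LOC105197535 and LOC105202373 in the ovary. Another tissue or organism whose share follows the number of Sb copies would give the same values and stays open, above all in the ovary, where ovary-specific genes fell with Sb. If a copy on the Sb haplotype made the reads, SB/Sb would have about 0.5 of the Sb/Sb level. The median ratio was 0.49 in the brain (quartiles 0.375 to 0.575) and 0.47 in the ovary (0.348 to 0.522). A candidate explanation is therefore that the Sb haplotype carries expressed copies of genes that the reference places elsewhere; regulation of the reference copies by a factor on Sb, in proportion to its copies, also stays open, since no genome sequence was used here.

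The many changed genes of Sb/Sb ovaries did not rest on 104D or on library size as the whole cause: 1521 genes were called without 104D and 1280 with the log2 library total in the model, against 1332. A smaller share of ovary-specific tissue in Sb/Sb ovaries may contribute. The library medians of 363 ovary-specific genes were lower in Sb/Sb than in SB/SB ovaries (exact permutation p = 0.00186). Evenly expressed genes were at -0.06 and -0.05, but TMM scaling holds so broad a set of genes near 0 in each library. They are therefore no separate control for the make-up of the sample. Of 118 changed ovary-specific genes, 21 were higher in Sb/Sb; these were defined only by their level against the brain, so they do not decide for or against a shift in the make-up of the sample. The age and the state of the ovaries were not analysed here, and a direct effect of Sb stays open.

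Other splits of the same libraries were fitted to see whether chance gives as many genes, with 100 splits per comparison, the real one included. A count is called rare among the splits where fewer than 5 of the 100 gave as many genes. This is a share per comparison, not adjusted over the comparisons. With 100 splits, shares close to this limit on either side cannot be told apart, so a rare count does not by itself exclude chance. Single other splits still called more genes where the highest other is above the real count. In the brain, the count was rare in this sense for Sb/Sb against SB/Sb (17 genes, 2 splits as large, highest other 26). It was also rare for Sb/Sb against SB/SB (103, 1, 10) and SB/Sb against monogyne (23, 2, 780). SB/Sb against SB/SB brains lay next to the limit (27, 4, 683), so nothing is concluded for them. The brain count was not rare for polygyne against monogyne SB/SB (1 gene, 7 splits, 1088) or for genes off the log2 mean (6, 18, 2620). In the ovary the count was rare for polygyne against monogyne SB/SB (228, 1, 92, and without 104D 113, 1, 14). It was also rare for Sb/Sb against SB/SB (1332, 2, 2344, and without 104D 1521, 3, 2994). The same held for SB/Sb against monogyne (2061, 1, 199, and without 104D 2396, 1, and 0 by edgeR). SB/Sb against SB/SB ovaries lay on either side of this limit, with 6 splits as large (244, highest other 1788) and 3 without 104D (179, highest other 1987), so nothing is concluded for it. The count was not rare for Sb/Sb against SB/Sb ovaries (14, 5, 3298, and without 104D 15, 13, 2396). Nor was it for genes off the log2 mean (14, 41, 2557, and without 104D 13, 9, 3517). Splits that called many times the real count point to a structure of the samples. Title numbers may be part of it, since ovary libraries of the same number were alike in part (mean r 0.2 against -0.017). Whether they account for those splits was not tested. With 104D in the fit, 99 other splits called genes for polygyne against monogyne SB/SB, SB/Sb against SB/SB and Sb/Sb against SB/SB ovaries. The medians were 36, 36 and 37 genes. Without 104D, 3, 9 and 9 other splits called any gene, with a median of 0 in each. Counts of that size therefore came with 104D whatever the grouping.

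In the fits of both tissues only 9 splits of the group labels and 5 of the tissue labels were run, too few for a share under 0.05. With 9 splits, the tissue difference had 335 genes for Sb/Sb against SB/SB, 3 for SB/Sb against SB/SB and 6 for SB/Sb against monogyne, each in 1 split and with 0 genes by edgeR in the highest other. It had 0 for polygyne against monogyne SB/SB and 0 for Sb/Sb against SB/Sb (edgeR; 527 and 892 at an unadjusted p under 0.05), as in all 9 splits. With 5 splits, brain against ovary had 9588 genes, against 0 in the highest other.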
